A study of Columba livia with 4 samples.

How the data were processed

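The series holds 4 samples of primary pigeon (Columba livia) melanocytes, the pigment-producing cells of the skin and feather: chromatin immunoprecipitated for the transcription factor SOX10, for acetylated lysine 27 of histone H3 (H3K27ac) and for trimethylated lysine 27 of histone H3 (H3K27me3), and an input of sheared chromatin that was not immunoprecipitated. There was 1 library per target. Per the labels' protocols, the medium held fetal bovine serum (10%), Nu-serum (5%), endothelin-3 (10 ng/mL), the phorbol ester TPA (85 nM) and cholera toxin (40 ng/mL). They were fixed in 1% formaldehyde for 15 min, the chromatin was sonicated to 300 to 500 bp on average, and the libraries were read as single 75 nt ends.

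The submitters' processing notes name bcl2fastq 2.20, Bowtie2 2.2.9, SAMtools 1.16 and MACS3 3.0.0, without their order or settings. The 3 deposited files are peak lists in the narrow format for SOX10 and the broad format for the histone marks, 1 list per library. Each peak has a score, which the authors' caller deposited as a whole number cut from 10 times the −log10 q and which was not used further, and a fold enrichment over local background, a ratio the authors deposited for the summit of each SOX10 peak and for the whole region of each histone peak. Each peak also has a p-value and a q-value, which the authors deposited as −log10. The largest q-value present was 0.0462 for SOX10, 0.0968 for H3K27ac and 0.0965 for H3K27me3, which lie under 0.05 for the narrow list and under 0.1 for both broad lists. The SOX10 peak names hold the words keepdupauto. The control library, the duplicate handling of the histone lists and the genome build are not given in the sources used here. Fold, p and q are the authors' values throughout and were used to describe, rank or filter peaks within a list.

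Peaks lie on scaffolds of the AKCR02 series. No genome or annotation of that assembly was used here, and the gene table at hand belongs to another assembly, so peaks are given by scaffold, start and end, counted from 1, and no gene is named. The 4 results planned on genes and sequence were therefore not run: position relative to genes, promoter states, the 13 gene lists and motifs at SOX10 summits. Scaffold lengths were replaced by the highest peak end of any list on that scaffold, called its span here, which is a lower limit. The spans came to 1088 Mb over 2200 scaffolds, and 93.3% of it lay on the 127 scaffolds with a span of at least 1 Mb. Runs of unknown bases could not be masked.

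From the lists, the number, width and covered bases of the peaks were computed. An overlap meant at least 1 shared base. Each overlap was compared with 1000 random placements, in which every interval kept its width and scaffold and took a uniform position in the span. The quintiles of H3K27ac peaks and the distances to the nearest region used 200 placements. A value outside the central 95% of placements was called higher or lower. Medians of the SOX10 fold in 4 chromatin classes were compared with 10000 random reassignments of the class labels. Peaks of a histone mark were merged into domains over gaps of up to 5 kb. Shares of peaks have exact 95% binomial intervals, which cover counting error only, and neighbouring peaks are not independent. With 1 library per target there is no replicate check, and no p-value across samples can be given. The placements describe these lists. Correlations across scaffolds were tested with 100000 permutations, two-sided.

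Total reads per library are not given in the sources used here. The depth behind a SOX10 peak was recovered from its fold and p. The caller's fold is (fragments + 1) / (background + 1) and its p is a Poisson tail, so both together fix the fragments at the summit and the local background. A whole number of fragments met the deposited −log10 p within 0.001 for all 6579 SOX10 peaks, with a largest error of 0.000645, and the next whole number missed by at least 0.0204. Summits held 13 to 330 fragments with a median of 33, for which the exact 95% Poisson interval is 22.7 to 46.3. Values of the broad lists are averages over a region and were not solved.

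The alternatives were stricter peak thresholds (−log10 q of at least 5 or fold of at least 5 for SOX10, −log10 q of at least 3 for the marks), the summit or 50% of the peak as the overlap, circular shifts, local placement 20 to 200 kb away (a uniform position was taken where no such move fitted, for 4.16% of SOX10 and 9.31% of H3K27ac placements), scaffolds of at least 1 Mb, and other merging gaps. The tests, the alternatives just listed and the rule for the named regions were fixed before the data were examined: the 15 SOX10 peaks of highest fold and the 10 longest domains of each mark. Analyses that use the recovered fragments, classes of scaffold span, scaffold density, quintiles, clustering, the position inside a region or the distance to the nearest one were added after the data were seen. On simulated data the placement test gave a mean fold of 0.999 ± 0.0388 (SD, 20 runs of 6579 intervals) for no enrichment, with 1 of 20 runs called higher, and 1.51 ± 0.0537 for a simulated 1.5, with 20 of 20 called. The simulated intervals were drawn by the same uniform placement as the comparison, so these runs check the calculation only. Clustered peaks, runs of unknown bases and unknown scaffold lengths were not simulated. The recovery of fragments returned the simulated number for 100% of 298 simulated peaks. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.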

Results

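Genome occupancy of SOX10, a transcription factor of the neural crest and its pigment and glial derivatives, was mapped in primary pigeon melanocytes beside 2 histone modifications. H3K27ac marks active promoters and enhancers, and H3K27me3 is laid down by Polycomb repressive complexes. The SOX10 list held 6579 peaks with a median width of 198 bp, the H3K27ac list 34223 peaks with a median of 721 bp, and the H3K27me3 list 36792 peaks with a median of 488 bp. They covered 1.48 Mb, 42.9 Mb and 37.7 Mb, which are 0.136%, 3.95% and 3.46% of the 1088 Mb spanned by the scaffolds. The median fold enrichment over local background, as the authors' caller gave it, was 3.35 for SOX10 (interquartile range 2.84 to 4.01), 3.82 for H3K27ac (3.09 to 5.37) and 3.27 for H3K27me3 (2.92 to 3.98). SOX10 summits held a median of 33 fragments over a median local background of 8.98. Each target had 1 library, so none of the values has a replicate error.

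The first comparison asked in which chromatin SOX10 peaks lay. SOX10 peaks lay mostly in acetylated chromatin: 3815 of 6579 peaks (58.0%, exact 95% interval 56.8 to 59.2%) overlapped an H3K27ac region, against 7.0% of randomly placed intervals (central 95% of 1000 placements, 6.41 to 7.55%). This was 8.28 times the expected number. On scaffolds of at least 1 Mb, 55.9% of SOX10 peaks overlapped H3K27ac against an expected 4.51%, a ratio of 12.4. The ratio was 15.1 on scaffolds over 10 Mb, 9.87 on those of 1 to 10 Mb, 4.36 on those of 0.1 to 1 Mb and 1.45 on those under 0.1 Mb, where placed intervals themselves overlapped H3K27ac in 46.2% of cases. All 4 ratios were called higher than random placement. The observed share itself was 53.6% on scaffolds over 10 Mb, 75.5% on those of 0.1 to 1 Mb and 66.8% on those under 0.1 Mb. Spans come from the same lists, and 208 H3K27ac peaks covered the whole span of their scaffold, where every placement overlaps. The lower ratios on short scaffolds therefore do not show weaker enrichment. SOX10 summits sat towards the middle of acetylated regions: of the 3492 summits inside an H3K27ac peak, 70.7% (69.2 to 72.2%) lay in its central 50%. The 2764 SOX10 peaks outside H3K27ac were nearer to it than placed intervals were, though most lay more than 2 kb away. Summits of these SOX10 peaks lay a median of 10753 bp from the nearest H3K27ac peak, against 25764 bp (24304 to 27033 bp) for placed summits outside H3K27ac. Within 2 kb lay 30.6% of the observed summits, against 9.87% (9.15 to 10.5%) of placed ones. Placed summits came from uniform positions of all SOX10 peaks, and local placement was not run for this distance.

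Seen from the acetylated regions, 3342 of 34223 H3K27ac peaks (9.77%, 9.45 to 10.1%) overlapped a SOX10 peak, against an expected 1.25%. The share rose with the strength of acetylation. In the lowest quintile of H3K27ac fold, 1.27% of peaks overlapped SOX10, or 2.23 times the expected number for those regions. In the highest quintile, with folds from 5.97 to 43.7, it was 26.1% (25.1 to 27.2%), or 9.93 times the expected number. By width, the share was 1.46% for the narrowest quintile and 29.0% for the widest, at 3.11 and 9.18 times the expected numbers. The fold of a SOX10 peak was almost unrelated to the H3K27ac fold of its region. Across the 3815 overlapping peaks Spearman's rho was 0.0773, outside the −0.0315 to 0.0315 given by the central 95% of permuted pairs. For the fragments at the SOX10 summit rho was 0.00289, inside the −0.0316 to 0.0314 of permuted pairs, and for the local background it was −0.0424, outside the −0.0319 to 0.0321. Peaks are not independent replicates.

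Taken over all peaks, SOX10 peaks lay in H3K27me3 regions less often than placed intervals. Of the 6579 peaks, 171 (2.60%, 2.23 to 3.01%) overlapped H3K27me3, against 5.47% (4.94 to 5.97%) of placed intervals, or 0.475 times the expected number. The ratio was 0.497 on scaffolds over 10 Mb, 0.367 on those of 1 to 10 Mb, 0.600 on those of 0.1 to 1 Mb and 0.578 on those under 0.1 Mb, each called lower than placement. The log2 difference between the enrichment in H3K27ac and that in H3K27me3 was 4.12, outside the central 95% of differences from placement (a ratio of 17.4). Of all SOX10 peaks, 3727 lay in H3K27ac alone, 83 in H3K27me3 alone, 88 in both and 2681 (40.8%) in neither. By quintile of the local background of the SOX10 peak, from lowest to highest, the share in H3K27ac was 48.3%, 52.8%, 58.2%, 64.8% and 66.0%. The share in H3K27me3 also differed with background: in the same order it was 8.34% (6.90 to 9.96%), 1.95% (1.28 to 2.84%), 0.847% (0.424 to 1.51%), 0.456% (0.167 to 0.989%) and 1.37% (0.816 to 2.16%). The lowest quintile lay above the 5.47% placed over all peaks, and the other quintiles lay below it. Placement was not run by quintile, so a shortage in H3K27me3 at low background was not shown.

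**Figure D1:**
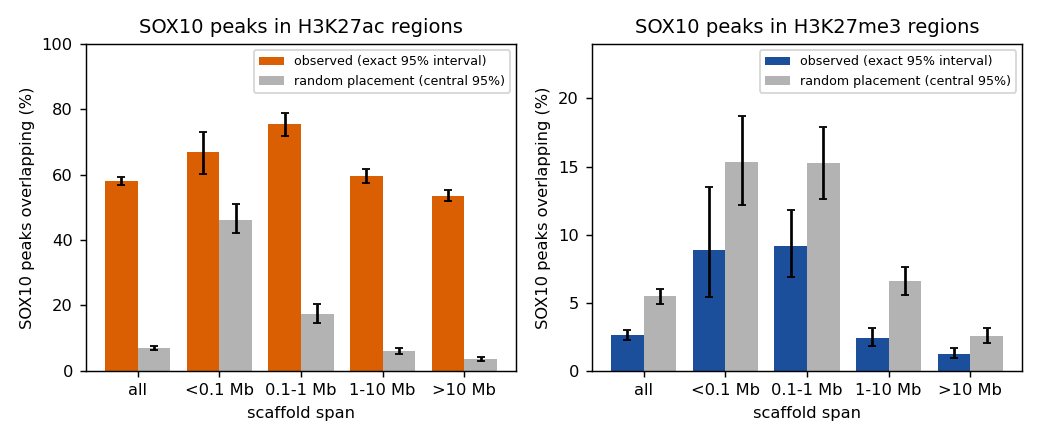
Percent of SOX10 peaks that overlap an H3K27ac region (left) or an H3K27me3 region (right), for all scaffolds and for 4 classes of scaffold span; coloured bars are the observed shares with exact 95% binomial intervals, grey bars the means of 1000 random placements with their central 95%. Observed shares lie above placement for H3K27ac (58.0% against 7.0% over all scaffolds) and below it for H3K27me3 (2.60% against 5.47%).

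Among the 15 SOX10 peaks of highest fold, which ran from 9.64 to 20.5, 11 lay in H3K27ac alone, 1 in both marks, 3 in neither and 0 in H3K27me3 alone. The strongest was on scaffold AKCR02000247.1 at 85376 to 85737, with a fold of 20.5, a −log10 q of 102.6 and 111 fragments over a background of 4.46, in a region of H3K27ac fold 15.2. The next, at 11248159 to 11248408 of AKCR02000019.1, had a fold of 16.6 and 78 fragments in a region of H3K27ac fold 12.3. A peak of fold 15.2 at 101630 to 102094 of AKCR02000286.1 held 105 fragments, and a peak of fold 15.7 lay at 924 to 1240 of AKCR02003322.1, a scaffold with a span of only 1.24 kb. The 3 strong peaks in neither mark were at 9274051 to 9274436 and 4123096 to 4123450 of AKCR02000019.1, with folds of 11.9 and 10.4, and at 4871975 to 4872185 of AKCR02000046.1, with a fold of 9.64. The peak with the most fragments among the 15, 162 over a background of 15.0, was at 5414237 to 5415127 of AKCR02000030.1 and had a fold of 10.2. The other peaks of the 15 had folds of 9.64 to 11.2 and lay on the scaffolds AKCR02000005.1, AKCR02000009.1, AKCR02000023.1, AKCR02000055.1, AKCR02000061.1, AKCR02000092.1 and AKCR02000152.1, the last in both marks.

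The second comparison was of SOX10 peak strength between chromatin classes. By fold, peaks in H3K27ac alone were slightly weaker than those in neither mark, with medians of 3.30 and 3.38. The difference of −0.0786 lay below the −0.0363 to 0.0416 of random class labels. Peaks in H3K27me3 alone and in both marks had higher median folds, 3.81 and 3.79, with differences of 0.425 and 0.411 that lay above the ranges of random labels (−0.223 to 0.237 and −0.209 to 0.234). By fragments at the summit the order turned round: the medians were 34 in H3K27ac alone, 32 in neither, 25.5 in both and 21 in H3K27me3 alone, each outside random labels against neither. The local background followed the same order, at 9.81, 8.63, 5.99 and 4.58 fragments. Of the 83 peaks in H3K27me3 alone, 20.5% lay at the lowest background of 3.77 fragments, against 2.09% of those in neither mark. A q-value cutoff admits only higher folds where the background is low, and only higher fragment numbers where it is high. The classes were not compared at like background, so neither order ranks them by SOX10 strength apart from background. The median −log10 q was 5.72 in H3K27ac alone, above the 5.42 of neither mark beyond random labels. The 4.52 of H3K27me3 alone and the 5.92 of both lay within the range of random labels around neither.

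**Figure D2:**
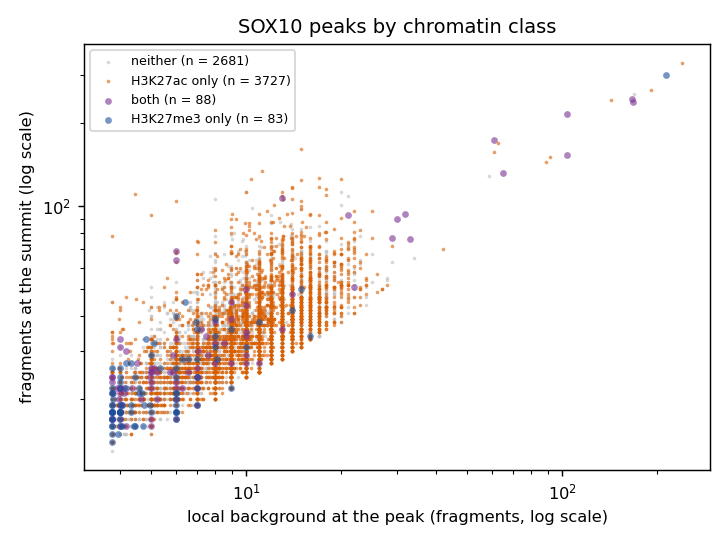
Fragments at the summit (vertical axis, log scale) against local background in fragments (horizontal axis, log scale) for each of the 6579 SOX10 peaks, coloured by chromatin class. Peaks in H3K27me3 alone gather at low background (median 4.58), and peaks in H3K27ac alone at a median of 9.81.

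The third comparison was between the 2 modifications of the same residue. They shared 1.94 Mb, which was 4.53% of the H3K27ac bases and 5.16% of the H3K27me3 bases. Of the 34223 H3K27ac peaks, 4277 (12.5%, 12.1 to 12.9%) touched an H3K27me3 region, against 11% (10.7 to 11.3%) of placed intervals, or 1.13 times the expected number. On scaffolds of at least 1 Mb the share was 7.09% against an expected 7.15%, inside the range of placements (6.88 to 7.45%). With peaks moved only 20 to 200 kb on these scaffolds the expected share was 7.52% (7.23 to 7.81%), and the observed share was called lower. With at least 50% of the H3K27ac peak covered, the share was 8.05% against 5.83%, and on scaffolds of at least 1 Mb 4.78% against 3.52%, both called higher.

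Merging over gaps of up to 5 kb gave 17608 H3K27ac domains with a median length of 1526.5 bp and 15208 H3K27me3 domains with a median of 891 bp. Domains of at least 20 kb numbered 504 for H3K27ac and 648 for H3K27me3, and held 23.9% and 40.9% of the bases of their mark. The 10 longest H3K27me3 domains were 161 to 403 kb long. The longest was at 100801 to 503624 of AKCR02000141.1, with 80.1% of its length under H3K27me3 peaks and 6.81% under H3K27ac. It held 3 SOX10 summits, the most of the 10. The next, of 277 kb at 422409 to 699546 of AKCR02000104.1, held no SOX10 summit, and a domain of 255 kb at 8949530 to 9204097 of AKCR02000027.1 had no base under H3K27ac. Together the 10 domains held 10 SOX10 summits, 0.455 per 100 kb, against 0.604 per 100 kb over the whole span, and 4 of them held none. This difference was not tested, and the whole span is not matched to the scaffolds of the domains. The 10 longest H3K27ac domains were 81.6 to 124 kb long and held 34 SOX10 summits, 3.49 per 100 kb, with at least 1 in each. The longest, at 48950 to 173001 of AKCR02000183.1, had 56.0% of its length under H3K27ac peaks, 22.4% under H3K27me3 and 5 SOX10 summits. The next, of 118 kb at 278360 to 396254 of AKCR02000093.1, had 8 summits, and the longest with no base under H3K27me3 was at 19278426 to 19361456 of AKCR02000003.1. Lengths depend on the merging gap: unmerged, the longest peaks were 31.0 kb for H3K27ac and 41.2 kb for H3K27me3.

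Most acetylated domains with a SOX10 summit held a single one. Of the 17608 merged H3K27ac domains, 3111 held at least 1 of the 4001 SOX10 summits that fell in them, more than the 2869 (2821 to 2917) expected for summits placed at random over the bases of these domains. Domains with at least 3 summits numbered 168, fewer than the 238 (217 to 258) expected, and those with at least 5 numbered 29, against 42.4 (33.0 to 53.0). The bases of a domain include the gaps between its merged peaks, whereas 3492 summits lay inside an H3K27ac peak. Placement did not hold this preference for peaks over gaps fixed, so these counts do not show that SOX10 summits are spread apart. The domain with the most summits had 9, inside the 8 to 15 of random placement. It spanned 3599075 to 3644343 of AKCR02000009.1, with 76.7% of its length under H3K27ac peaks and no base under H3K27me3. A domain of 42.9 kb at 62241 to 105172 of AKCR02000247.1 held 8 summits, among them the strongest SOX10 peak. Both domains were picked after their values were seen.

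**Figure D3:**
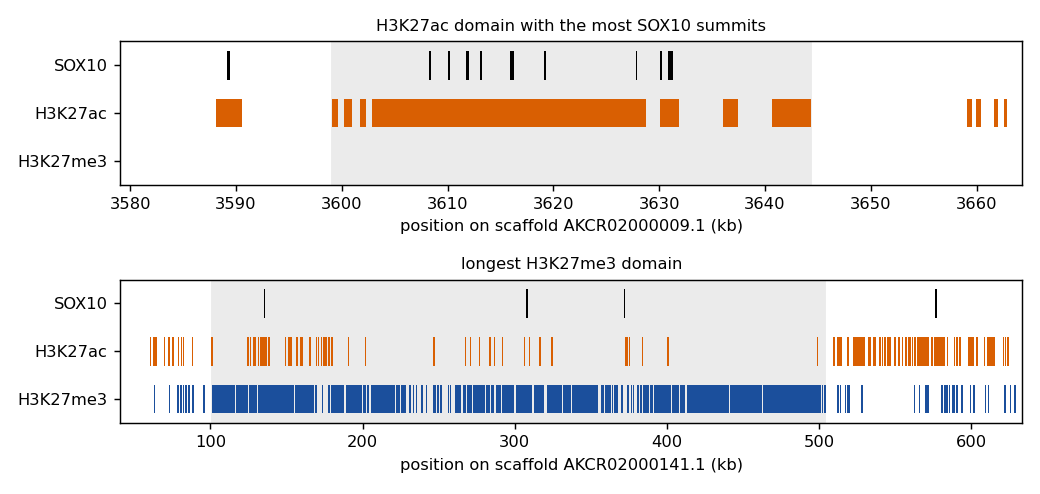
Peaks of the 3 lists along 2 regions, with the position in kb on the horizontal axis and a row per target; grey marks the merged domain, and the narrowest peaks are drawn wider than to scale so that they can be seen. Above, the H3K27ac domain with 9 SOX10 summits; below, the longest H3K27me3 domain (403 kb), which is followed by a dense run of H3K27ac peaks.

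Across the 127 scaffolds of at least 1 Mb, SOX10 peak density ran from 0 to 18.6 per Mb with a median of 5.93. It rose with the share of the scaffold under H3K27ac (Pearson's r = 0.88, Spearman's rho = 0.83) and under H3K27me3 (r = 0.55, rho = 0.61). The shares under both marks rose together (r = 0.65, rho = 0.61). The permutation p was 1e-05 for each of these 6 coefficients, the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over the 6. Scaffolds are not independent replicates. Without the 2 scaffolds farthest from the median of the horizontal axis, r was 0.83, 0.47 and 0.56. With the H3K27ac share held fixed, the rank correlation of SOX10 density with H3K27me3 was 0.23 (permutation p = 0.0107). Scaffold AKCR02000122.1, with a span of 1.29 Mb, was picked after its values were seen and was highest on these 3 measures, with 18.6 SOX10 peaks per Mb, 15.1% under H3K27ac and 40.4% under H3K27me3.

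**Figure D4:**
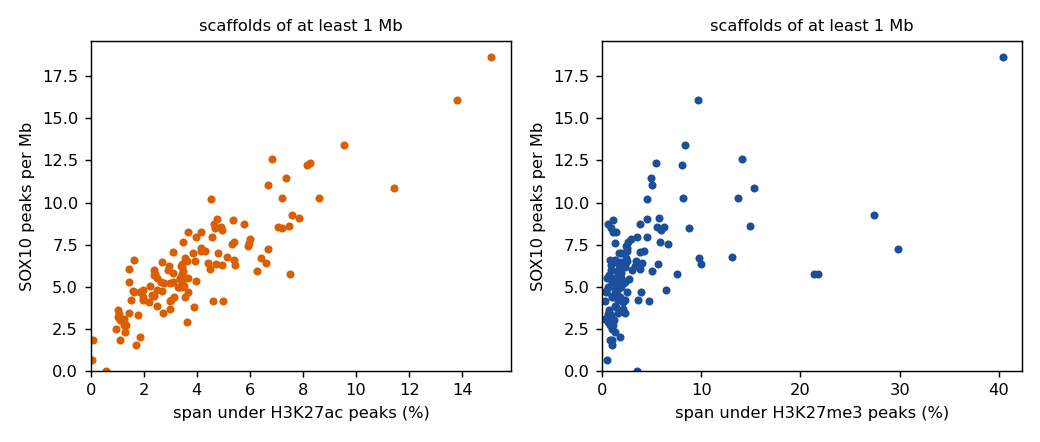
SOX10 peaks per Mb (vertical axis) against the percent of the scaffold span under H3K27ac peaks (left) or H3K27me3 peaks (right), 1 point for each of the 127 scaffolds of at least 1 Mb. Density rises with both shares, more closely with H3K27ac (r = 0.88) than with H3K27me3 (r = 0.55).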

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

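The settings with summit fragments, high background removed, 1 Mb scaffolds for SOX10 strength, and 1 Mb scaffolds combined with a threshold, 50% coverage or local placement, and all settings on scaffolds under 1 Mb were chosen after seeing the data. Of 70 recalculations, 53 gave the same direction and call or stayed within 1.5 times the first count. In 10 alternatives SOX10 peaks stayed above placement in H3K27ac (log2 observed over expected 2.62 to 3.63) and below it in H3K27me3 (−1.33 to −0.78), and the difference between the marks ranged from 3.51 to 4.89. A further one, without SOX10 peaks in both marks, was not counted: it drops observed but not placed overlaps, so its lower H3K27me3 value (−2.03) and larger difference (5.11) say nothing about stability. For H3K27ac peaks in H3K27me3 regions the log2 value of 0.18 turned to −0.013, inside the range of placements, on scaffolds of at least 1 Mb, reversed to −0.085 with local placement on them, and lay between 0.13 and 0.47 in the other 8 alternatives. The difference in SOX10 strength between H3K27ac alone and neither mark reversed to 0.30 with −log10 q and to 2 with fragments at the summit. That between H3K27me3 alone and neither lost its call with −log10 q, at −0.91 inside the range of random labels, and reversed to −11 with fragments. That between both marks and neither lost its call with −log10 q (0.50) and reversed to −6.5 with fragments. The cause was not tested. A −log10 q of at least 5 left 3718 SOX10 peaks and a fold of at least 5 left 566. A −log10 q of at least 3 left 22007 H3K27ac and 10153 H3K27me3 peaks. Without merging there were 34223 H3K27ac and 36792 H3K27me3 domains, the longest 31.0 kb and 41.2 kb, and with gaps of up to 12 kb the longest H3K27ac domain was 251 kb. The 15 planned settings for genes, promoters, gene lists and motifs were not run, since no genome or annotation of the build was used here. No replicate could be left out. Chance values that the 3 lists would share through a common control could not be simulated from peak lists. No paired analysis was possible because each target has 1 library. Depth limits the SOX10 list: no listed summit held fewer than 13 fragments, and the number needed to pass the cutoff rises with local background. Sites of lower occupancy are not covered, and this limit is not the same at all backgrounds.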

Other observations

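The tests of the fold inside H3K27me3, of the strict H3K27ac and H3K27me3 calls, 50% coverage and local moves on long scaffolds, of local moves on shorter scaffolds, of the background steps and of the H3K27me3 overlap as a sign of input depth were chosen after the result was seen, as were the draws of long domains, the ranking of histone peaks and the peaks of high background. Long acetylated and long trimethylated domains shared scaffolds more often than random draws. Of the 10 longest H3K27ac and the 10 longest H3K27me3 domains, 4 scaffolds carried 1 of each. The 2 domains were 5.6 kb apart on AKCR02000141.1, 18.1 kb on AKCR02000043.1, 261 kb on AKCR02000122.1 and 703 kb on AKCR02000061.1. When 10 domains of each mark were drawn at random from those of at least 20 kb, 0.773 shared scaffolds came on average, and 0.280% of 10000 draws gave 4 or more. The draws were not matched on domain length or on the share of a scaffold under each mark. Those shares rose together across scaffolds of at least 1 Mb (rho = 0.61), so the draws do not show a link between long domains beyond this. The strongest histone peaks often lay on very short scaffolds: of the 10 of highest fold, 7 H3K27ac and 6 H3K27me3 peaks were on scaffolds with a span under 10 kb.

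SOX10 peaks lay in H3K27ac regions 8.28 times as often as placed intervals. A shared preference for the same broad stretches of the genome is argued against by moving SOX10 peaks only 20 to 200 kb, which left a log2 excess of 2.78 over all scaffolds and of 3.15 on those of at least 1 Mb, where every peak had room for the move. Unusual input depth, called as peaks in every list, is argued against as the whole cause by the shortage of SOX10 peaks in H3K27me3 regions (log2 −1.07). The share of SOX10 peaks in H3K27me3 itself differed with local background, at 8.34% in the lowest quintile and 1.37% in the highest. The shortage therefore does not test an effect of input depth that differs between the marks. Non-specific recovery of open chromatin in the SOX10 library stays open, since the rho of 0.0773 between SOX10 fold and H3K27ac fold falls between the values named for and against it, the share of SOX10 peaks in H3K27ac rose from 48.3% to 66.0% between the lowest and highest quintile of local background while that background fell slightly with the H3K27ac fold of the region (rho −0.0424), and no immunoprecipitation without a specific antibody was analysed here. Binding of SOX10 at active elements is the biological alternative, and it was not tested apart from this.

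The fold enrichment of SOX10 peaks and their fragment number ranked the chromatin classes in opposite orders. The median local background was 1.14 times that of neither mark at peaks in H3K27ac alone and 0.53 times at peaks in H3K27me3 alone. Fragments and background were both solved from the deposited fold and p, so with opposite orders of fold and fragments these ratios follow by arithmetic and are no independent evidence for an explanation. Why the background differs between the classes was not tested, and no biological explanation was tested.

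H3K27ac peaks touched H3K27me3 regions 1.13 times as often as placed intervals. The excess over all peaks was gone on scaffolds of at least 1 Mb (log2 −0.013), the result named beforehand for short scaffolds that carry both lists. Placement kept each peak on its scaffold, however. The result therefore shows where the excess lay, not that carrying both lists accounts for it. Under other definitions an excess remained on scaffolds of at least 1 Mb. There log2 was 0.17 with −log10 q of at least 3 in both lists and 0.44 with at least 50% of the H3K27ac peak covered. Weak calls are argued against by the strict lists on all scaffolds (0.13). With local placement 0.15 was left over all scaffolds. For the 3013 peaks on scaffolds under 1 Mb with room for every move, 0.28 was left, against 0.25 with uniform positions. The expected shares were close, at 22.9% with local and 23.3% with uniform positions. On spans under 1 Mb, moves of up to 200 kb cover much the same ground as uniform positions. Little can therefore be said about shared broad stretches from these 3013 peaks. The other 4471 peaks on scaffolds under 1 Mb had a log2 of 0.41 with uniform positions. They lacked room for every move, so local placement could not fully test them. On scaffolds of at least 1 Mb local placement gave −0.085 at 1 shared base, with no excess to explain by that definition. It was not run there for the other definitions. Mixed cells, different alleles and true co-occurrence remain open, and no biological explanation was tested.

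The recovered SOX10 background fell on regular steps. Of the 6449 backgrounds above the lowest value, 63.6% were whole multiples of 0.998 within 0.005 of a step, for the best of all steps tried from 0.9 to 1.1, against a median of 0.217% over these steps. This is consistent with whole fragments of a control library scaled by a single factor, and the control library itself was not analysed here. The 16 SOX10 peaks with a background over 50 fragments had folds of only 1.38 to 2.83. Of these, 6 lay in both marks, and 6 were on scaffolds of at least 1 Mb, against 87.9% of all SOX10 peaks, so their overlap has no like group for comparison here.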
